A study of Mus musculus with 24 samples.

How the data were processed

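Liver RNA from 24 female mice, 4 in each of 6 groups of genotype and diet, was sequenced from polyA-selected libraries. Per the labels' protocols, RNA was extracted with TRIzol and cleaned on columns, and libraries were made with a KAPA mRNAseq Hyperprep kit and dual-index adapters that carry molecular identifiers. The protocols also give an RNA integrity number above 8 for each sample. The deposited values are whole-number counts of reads per gene, not normalized by the authors as far as the values show, and the file names 55335 genes by Ensembl identifier. Trimmomatic, STAR and the GRCm38 build are named in the submitters' processing notes, with no usable version. The name of the deposited counts calls them stranded gene read counts from STAR. The strand direction and whether molecular identifiers were used to remove duplicates are not given in the sources used here. No further step was taken to separate overlapping or antisense genes, and intervals and floors cover counting error only. The 4 summary entries that name no gene (unmapped, multimapping, no feature, ambiguous) held 21.5% to 30.1% of entries per library and were left out of library sizes and tests. Gene symbols, categories and coordinates were those given with the deposited counts. Gene length and GC content came from GENCODE annotation of GRCm38.

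Counts on genes ranged from 12009432 to 20108831 per library. Genes were filtered with edgeR's filterByExpr by group, leaving 13281. Main tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, 1 quasi-likelihood fit of all 24 libraries with a mean per group, 18 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. Contrasts were KD and MCT against control diet and KD against MCT in each genotype, 3xTg against WT on each diet, and the differences between the genotypes in the KD and MCT responses. Gene lists of pathways and cell types were fixed before the data were examined, and those with at least 5 tested genes, 40 in all, were tested with limma 3.58.1 camera at a preset correlation of 0.01 and again with an estimated correlation. Counts adjusted over the list alone use Benjamini-Hochberg within that list. CPM values are TMM-normalised means ± SD over 4 livers, except library sums, which use raw library totals.

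Genes named in the text follow a rule set before the data were examined. It takes the 5 highest and 5 lowest log2 fold changes per contrast among called genes with an average of at least 1 CPM and no overlap between the groups, passing over symbols of unnamed models. It adds up to 4 called members of each list with the smallest adjusted p, and 31 fixed metabolic and genotype genes, of which 30 were tested. For the differences between responses it takes the 10 smallest adjusted p. A selection of these genes is printed, and results for some are not reported here. A skeletal muscle list was added after the data were seen.

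Libraries were checked for identical or near-identical pairs, and the smallest chi-square per gene between replicates was 27.3, so none was counted as a duplicate. Exact permutation tests compared 8 library measures in 9 contrasts, 72 tests in all, and 36 more on Neat1, Xist, Ptprc and the Kupffer cell list in the same contrasts were added after the data were seen. The tests were checked on simulated counts for KD against control diet in 3xTg with 13281 genes, where 200 genes were changed. Of 50 genes each at log2 changes of 2, 1, -1 and -2, the test recovered 94%, 72%, 58% and 92%, and it called 9 unchanged genes and 0 genes in an unchanged contrast.

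Alternatives fixed before the data were examined were edgeR with RLE size factors, no expression filter, DESeq2 1.42.0, a fit of the compared groups alone, a replicate block, an estimated list correlation and leaving out each library. Added after the data were seen were a legacy quasi-likelihood fit, scaling by library size alone, and a pancreas score or a clock score as covariate. Also added were offsets for GC content and gene length (values for 99.97% of tested genes), and leaving out the 6 libraries with more than 100 CPM of pancreas transcripts, or 3xTg KD replicates 2 and 3, or each pair of KD livers of 1 genotype. Results of other splits of the livers used all 35 splits for 4 against 4, and 100 draws for the differences between responses, repeated after the data were seen with each gene's mean genotype effect as an offset. Shared control libraries were modelled with 20 simulated sets of unchanged groups.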

Results

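Liver polyA RNA was sequenced from 24 female mice, 4 in each of 6 groups. The groups crossed 2 genotypes with 3 diets. Wild-type (WT) mice were B6129SF2/J. The 3xTg-AD (3xTg) mice, a model of Alzheimer's disease, carry transgenes for mutant human APP and tau. Mice were 3 months old when they began 6 months on a control diet, a ketogenic diet (KD) without carbohydrate, or a control diet in which part of the fat was medium-chain triglyceride (MCT). By energy source the control diet held 70% carbohydrate, 20% long-chain triglyceride and 10% protein. The KD held 90% long-chain triglyceride and 10% protein, and the MCT diet 70% carbohydrate, 10% long-chain and 10% medium-chain triglyceride and 10% protein. The labels give 4 mice per group, so the spread between libraries is between animals. Counts on genes ranged from 12009432 to 20108831 per library, over 55335 annotated genes, of which 13281 passed the expression filter.

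Several libraries held transcripts of other tissues or cells. Exocrine pancreas transcripts, summed over 17 listed genes, reached 1044, 16343 and 4986 CPM (read counts scaled by library size) in WT KD replicates 1, 2 and 4, 17765 in WT MCT replicate 3, and 2992 and 9297 in 3xTg MCT replicates 3 and 4. The other 18 libraries, including all 8 control livers, held at most 31.4 CPM. Neutrophil transcripts summed to 96.1 and 107 CPM in 3xTg KD replicates 2 and 3, against 15.7 and 8.03 in the other two livers of that group. The group mean was 56.6 ± 51.9 CPM (SD, n = 4) against 6.94 ± 0.789 in 3xTg control livers (exact permutation p = 0.0286, two-sided, adjusted p = 0.206 over 72 such tests). The 3xTg KD group had mitochondrially encoded transcripts at 6.58% ± 0.579 of gene counts, against 9.50% ± 3.26 in 3xTg control livers (exact permutation p = 0.0857, adjusted p = 0.363). Its TMM scaling factors averaged 1.24 ± 0.0582 against 1.01 ± 0.0670 (exact permutation p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.206). Measures added after the data were seen were Neat1 and Xist, RNAs retained in the nucleus, Ptprc, a gene of leukocytes, and the summed Kupffer cell and macrophage list. In 3xTg KD livers Neat1 averaged 14.0 ± 3.48 CPM against 5.64 ± 0.697 in 3xTg control livers, and Xist 363 ± 90.6 against 191 ± 40.9 (SD, n = 4, exact permutation p = 0.0286 each, adjusted p = 0.103 over 36 added tests). WT control livers reached as high, with Neat1 at 18.7 ± 17.2 CPM (up to 41.7) and Xist at 385 ± 315 (up to 825), the highest values in WT control replicates 3 and 4.

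**Figure D1:**
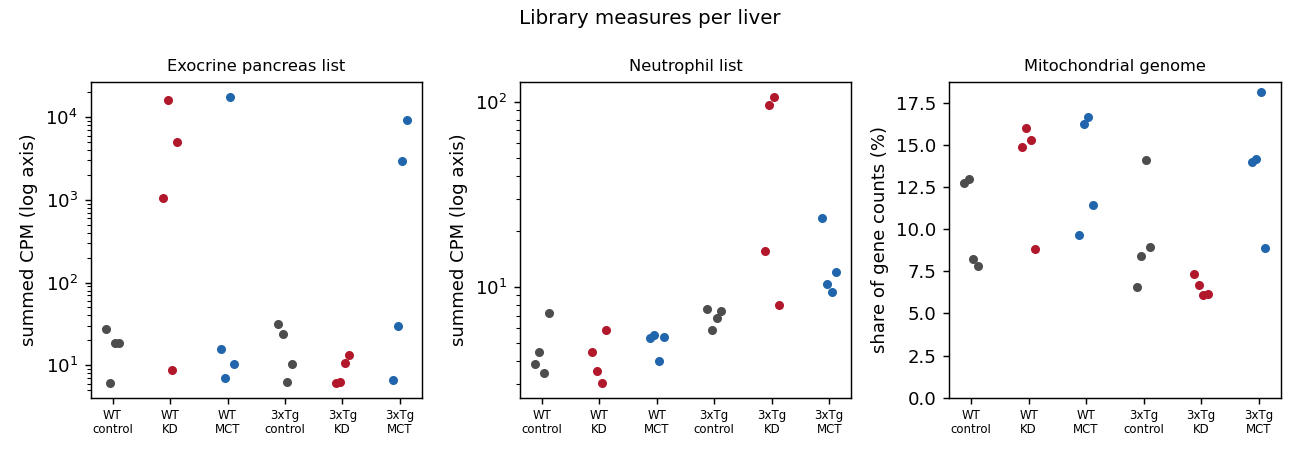
Each point is a liver (4 per group) in 3 panels, giving summed CPM of the exocrine pancreas list (log axis), summed CPM of the neutrophil list (log axis) and the mitochondrially encoded share of gene counts (%). Pancreas sums lie above 1000 CPM in 6 KD or MCT livers and at or below 31.4 CPM in the other 18, and 3xTg KD replicates 2 and 3 hold the 2 highest neutrophil sums.

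Fold changes below are log2 values relative to the median of all tested genes, given ± SE with n = 4 livers per group. Adjusted p is edgeR's quasi-likelihood p after Benjamini-Hochberg adjustment. With TMM these medians lay near 0. Scaling by library size alone put the median of all genes at 0.31 for KD against control diet in 3xTg, at 0.43 for KD against MCT in 3xTg, and at 0.43 for 3xTg against WT on KD. It put the median at 0.45 for the difference between the KD responses, at -0.15 for KD in WT and at -0.12 for MCT in 3xTg.

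In WT liver, KD raised the triglyceride assembly and storage genes Mogat1 and Fitm2 and lowered fatty acid synthesis genes such as Fasn and Scd1. Mogat1, a monoacylglycerol acyltransferase (ENSMUSG00000012187.13, chromosome 1, 78510991 to 78538173 on GRCm38), rose from 1.42 ± 0.384 to 14.0 ± 2.86 CPM (SD), a log2 fold change of 3.30 ± 0.33, adjusted p = 1.23e-05. Elovl3, a fatty acid elongase (3.14 ± 0.60, adjusted p = 0.0190), Kbtbd11 (2.68 ± 0.40, adjusted p = 0.00224), Inhbe (1.60 ± 0.29), Krt23 (2.53 ± 0.48) and Fitm2, a lipid droplet protein (1.01 ± 0.19), rose as well. Scd1, the stearoyl-CoA desaturase, fell from 4846 ± 1996 to 715 ± 313 CPM (-2.76 ± 0.54, adjusted p = 0.0190), with Fasn (-1.97 ± 0.39), Elovl6 (-2.61 ± 0.56), Acaca (-1.13 ± 0.25), Pklr, the liver pyruvate kinase (-1.18 ± 0.27), and Pnpla3 (-4.44 ± 0.77). Outside lipid metabolism, Atp2b2 (-2.72 ± 0.39), Lrtm1 (-3.76 ± 0.73) and Chrna4 (-5.29 ± 1.17) fell.

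Of 23 measured genes of de novo lipogenesis and desaturation, 7 fell and 16 were not called. In all 12 fell when adjusted over the list alone (median -0.92, camera adjusted p = 1.70e-08, adjusted p = 0.155 with an estimated correlation). Of 26 PPARA targets of peroxisomal and microsomal fatty acid oxidation, Pex11a rose (1.15 ± 0.23) and 25 were not called. There 9 rose when adjusted over the list alone (median 0.50, camera adjusted p = 3.22e-10, adjusted p = 0.0526 with an estimated correlation). The mitochondrial beta-oxidation list was higher with no member called over all genes and 8 of 19 adjusted over the list alone (median 0.29, camera adjusted p = 1.22e-08, adjusted p = 0.0526 with an estimated correlation). Of 19 lipid droplet genes, Mogat1 and Fitm2 rose, and 6 adjusted over the list alone (median 0.61, camera adjusted p = 2.60e-08, adjusted p = 0.0526 with an estimated correlation). Ketogenesis genes had a median of 0.25 with none of 7 called over all genes or adjusted over the list alone (camera adjusted p = 0.00647, adjusted p = 0.0526 with an estimated correlation). Of 30 genes fixed for reporting that were tested, 26 were not called, with Cidec (3.04 ± 0.87) the highest of these. The exocrine pancreas list had a median of 10.00, with all 16 measured members higher adjusted over the list alone, none of them called over all genes. Pnliprp2, a pancreatic lipase-related gene, was called (10.09 ± 2.44, adjusted p = 0.0472), and 3 of the 4 WT KD livers hold pancreas transcripts. The list's camera adjusted p was 0.00140, and adjusted p = 0.608 with an estimated correlation.

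Other cell types moved as lists in WT as well. Endothelial markers were higher on KD (median 0.25, camera adjusted p = 7.23e-05), as were stellate cell markers (median 0.27, camera adjusted p = 0.0114), and cell cycle genes were lower (median -0.59, camera adjusted p = 0.000137). None of these 3 lists held with an estimated correlation (adjusted p = 0.130 to 0.475). The stellate cell call was lost without WT control replicate 4 or WT KD replicate 4 (camera adjusted p = 0.169 and 0.240). Neat1 and Xist averaged lower on KD, at 5.36 ± 1.32 and 169 ± 47.9 CPM, than in WT control livers (exact permutation p = 0.171 and 0.229), a direction that is not past the spread between livers and opposite to that in 3xTg.

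In total 86 genes changed with KD in WT, 48 upward and 38 downward. Scaling by library size alone called 93, 27 upward and 66 downward. Without the libraries holding pancreas RNA, which leaves 1 WT KD liver that is taken to vary like the other groups, 4 genes were called. Mogat1 was among them, and the other called genes named here were not. DESeq2 called 266. Leaving out WT control replicates 1 to 4 in turn gave 46, 48, 36 and 13 genes, and WT KD replicates 1 to 4 36, 14, 27 and 49. The calls of Mogat1, Kbtbd11 and Atp2b2 held without each of the 8 livers in turn. Pnpla3 lost its call without WT KD replicate 2, Inhbe without WT control replicate 4 and Elovl3 without WT control replicate 1 or 4, and the remaining called genes named here lost theirs without at least 3 of the livers.

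In 3xTg liver, KD raised the ketone body genes Acat1 and Bdh1 and the triglyceride assembly gene Mogat1, and lowered lipogenic genes such as Fasn and Acaca. Acat1 (ENSMUSG00000032047.5, chromosome 9, 53580522 to 53610382) rose from 389 ± 45.6 to 944 ± 180.1 CPM (1.28 ± 0.19, adjusted p = 0.000497) and Bdh1, a ketone body dehydrogenase, rose by 0.78 ± 0.20 (adjusted p = 0.0270). Mogat1 (4.02 ± 0.36, adjusted p = 1.33e-06), Sema5b (4.56 ± 0.57, adjusted p = 7.50e-05), Cidec (3.85 ± 0.85), Plin4 (3.07 ± 0.60), Fitm1 (2.68 ± 0.56), Elovl3 (3.22 ± 0.60), Krt23 (3.54 ± 0.52) and Fgf21, a hepatokine (1.27 ± 0.34), rose. Fasn (ENSMUSG00000025153.9, chromosome 11, 120805846 to 120824547) fell from 1443 ± 759.6 to 199 ± 119 CPM (-2.86 ± 0.40, adjusted p = 0.000310). Acaca (-2.48 ± 0.26, adjusted p = 1.39e-05), Pklr (-2.50 ± 0.28, adjusted p = 2.25e-05), Elovl6 (-4.02 ± 0.59), Scd1 (-2.52 ± 0.53), Pnpla3 (-4.07 ± 0.73), the leptin receptor Lepr (-3.09 ± 0.34, adjusted p = 2.25e-05) and the fatty acid binding protein Fabp5 (-4.29 ± 0.72) fell.

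**Figure D2:**
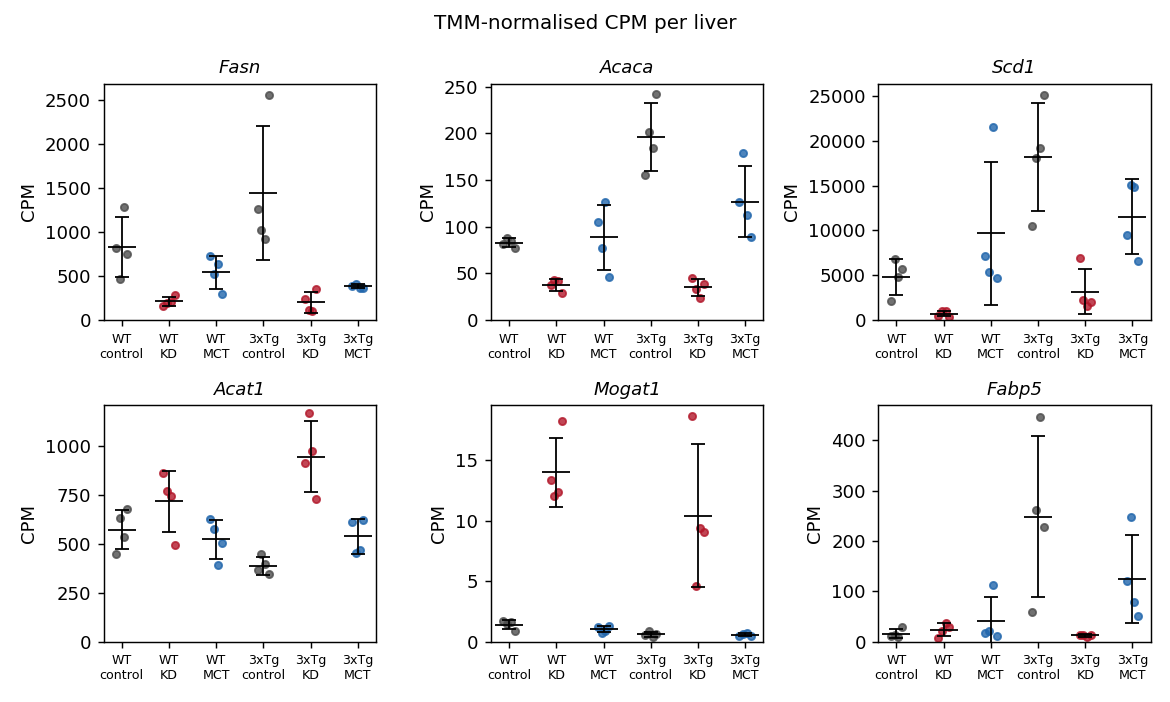
TMM-normalised CPM per liver (vertical axis, from 0) for 6 genes in the 6 groups. Points are livers (4 per group), with the group mean and SD as dash and bars, and Fasn in 3xTg livers averages 1443 CPM on control diet and 199 CPM on KD.

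Of 7 ketogenesis genes 3 rose, 4 adjusted over the list alone (median 0.68, camera adjusted p = 8.10e-06, adjusted p = 0.00662 with an estimated correlation). Of the 26 PPARA targets 10 rose, with Crot (1.17 ± 0.21), Pex11a (1.30 ± 0.23) and Hsd17b4 (0.68 ± 0.12) among them. The count was 17 adjusted over the list alone (median 0.82, camera adjusted p = 2.58e-13, adjusted p = 0.0368 with an estimated correlation). Of 19 beta-oxidation genes 7 rose, led by Etfdh (0.89 ± 0.13) and Acadm (1.12 ± 0.18). In this list 10 rose and 1 fell adjusted over the list alone (median 0.45, camera adjusted p = 1.21e-07, adjusted p = 0.0455 with an estimated correlation). Of 9 medium-chain fatty acid activation genes 3 rose, 4 adjusted over the list alone (median 0.59, camera adjusted p = 0.000751, adjusted p = 0.0455 with an estimated correlation). Lipogenesis genes fell in 12 of 23 cases, 17 adjusted over the list alone (median -1.50, camera adjusted p = 3.36e-17, adjusted p = 0.0368 with an estimated correlation). Of 19 lipid droplet genes 7 rose, 11 adjusted over the list alone (median 0.92, camera adjusted p = 4.88e-06, adjusted p = 0.0711 with an estimated correlation). Glycolysis and glucose uptake showed 3 of 15 lower, Pklr, Khk (-1.29 ± 0.21) and Slc2a2, the liver glucose transporter (-0.91 ± 0.19), and 1 higher, Ldha (0.57 ± 0.16). When adjusted over the list alone 7 were lower and 1 higher (median -0.52, camera adjusted p = 0.000129, adjusted p = 0.213 with an estimated correlation).

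Of 27 complement and coagulation genes 8 fell, 15 adjusted over the list alone (median -0.45, camera adjusted p = 4.52e-11, adjusted p = 0.0455 with an estimated correlation). F10, coagulation factor X, fell by 1.01 ± 0.19. Of 12 hepatocyte markers 3 fell, Ahsg (-0.71 ± 0.20), Ambp (-0.74 ± 0.17) and Serpina1a (-0.81 ± 0.22), the last with close paralogs that can share its reads. The count was 8 adjusted over the list alone (median -0.62, camera adjusted p = 2.08e-07, adjusted p = 0.111 with an estimated correlation). In the same comparison Neat1 and Xist were higher, and Kupffer cell and macrophage markers were higher as a list, with none of 18 called and 4 adjusted over the list alone (median 0.32, camera adjusted p = 0.00243, adjusted p = 0.442 with an estimated correlation). That call was lost without 3xTg KD replicate 2 (camera adjusted p = 0.0670). Nuclear-encoded respiratory chain genes fell in 3 of 40 cases, 4 adjusted over the list alone (median -0.19, camera adjusted p = 0.000115, adjusted p = 0.442 with an estimated correlation). Their median became 0.11 with library-size scaling, which put all genes at 0.31, so the sign of this median depends on the scaling. That it stayed below the median of all genes says little, as this scaling shifts all genes nearly alike. Of 5 measured neutrophil markers 3 rose, S100a8 (3.06 ± 0.63), S100a9 (2.81 ± 0.58) and Ngp (4.59 ± 0.92), with the highest sums in 3xTg KD replicates 2 and 3. The count was 4 adjusted over the list alone (median 2.81, camera adjusted p = 0.00317, adjusted p = 0.361 with an estimated correlation). Of the 30 genes fixed for reporting, 21 were not called, including Cpt1a (0.60 ± 0.23, adjusted p = 0.135) and Plin2 (0.92 ± 0.29, adjusted p = 0.0668).

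KD changed 716 genes in 3xTg liver, 378 upward and 338 downward, and with library-size scaling 1762, 1651 upward and 111 downward. Leaving out 1 liver gave 403, 392 and 389 without 3xTg control replicates 1, 2 and 3, and 470, 374 and 270 without 3xTg KD replicates 1, 2 and 3. Without both KD replicates 2 and 3 it was 75, and without the other 5 pairs of KD livers 89 to 633. The calls named here held in each of the 8 single omissions, with 7 exceptions. Bdh1 and Fgf21 were lost in 5, Ldha, Ahsg and Serpina1a in 6, Ambp without 3xTg KD replicate 3 and Cidec without 3xTg KD replicate 1. Fewer calls held without both KD replicates 2 and 3. There 184 of 332 values of named genes lost their call, over all contrasts with 3xTg KD and including values not called in the main fit. The neutrophil and Kupffer cell lists lost their calls without both KD replicates 2 and 3 (camera adjusted p = 0.327 and 0.289).

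Between genotypes the KD responses shared 44 called genes, 43 of them changed in the same direction. Shared upward genes numbered 27 against 1.37 for independent lists, and shared downward genes 16 against 0.967 (Fisher's exact test of the overlap, p = 3.32e-33). That test takes all 44 shared genes whatever their direction and treats genes as independent, which they are not. The comparisons share no libraries. Across all 13281 genes, which are not independent replicates, the fold changes had a Pearson's r of 0.0749. This moved with single livers, from -0.0433 without 3xTg KD replicate 4 to 0.192 without 3xTg control replicate 1. Without the libraries holding pancreas RNA it was -0.0173. In that setting 3 genes were shared, and without single livers 9 (WT control replicate 4) to 37. The test of the difference itself called 1 gene, Arl4d, a small GTPase (ENSMUSG00000034936.2, chromosome 11, 101665541 to 101667832), whose KD response was higher in 3xTg than in WT by 3.43 ± 0.56 (adjusted p = 0.0404). Leaving out single livers gave 124 genes without 3xTg KD replicate 4, 47 without WT control replicate 1, 15 without WT KD replicate 4, 6 without WT control replicate 2 and 0 in the other 12 cases. At an unadjusted p under 0.05 the full test gave 1939 genes, and DESeq2 called 253. The Arl4d call was lost without any single 3xTg control liver, without WT control replicate 3 or 4, without 3xTg KD replicates 1, 2 or 3, and without WT KD replicates 1, 2 or 3. It was called on KD in both genotypes, at 1.73 ± 0.39 in 3xTg and -1.70 ± 0.40 in WT.

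MCT feeding left no gene called by edgeR in WT, with 803 genes at an unadjusted p under 0.05 and 18 called by DESeq2. Without WT MCT replicate 1 it called 1. In 3xTg edgeR likewise called none, with 855 genes at an unadjusted p under 0.05 and 24 called by DESeq2. Cholesterol synthesis and uptake genes were nonetheless lower as a list on both backgrounds. In WT the list had 22 of 24 members below 0 and none called over the list alone (median -0.68, camera adjusted p = 8.83e-12, adjusted p = 0.420 with an estimated correlation). Sqle, the squalene epoxidase of that pathway, stood at -0.93 ± 0.35, adjusted p = 0.772. In 3xTg all 24 members were below 0, 5 adjusted over the list alone (median -0.76, camera adjusted p = 1.76e-20, adjusted p = 0.0913 with an estimated correlation). There Sqle stood at -1.50 ± 0.36, adjusted p = 0.367.

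In 3xTg the lipogenesis list was lower on MCT, with 11 of 23 members lower adjusted over the list alone and none over all genes (median -0.63, camera adjusted p = 1.37e-15, adjusted p = 0.0913 with an estimated correlation). Fasn stood at -1.91 ± 0.39, adjusted p = 0.352. B and plasma cell markers were higher (median 0.89, camera adjusted p = 2.40e-07, adjusted p = 0.160 with an estimated correlation). Adipocyte markers were higher too (median 2.29, camera adjusted p = 0.000142, adjusted p = 0.127 with an estimated correlation), as were all 16 exocrine pancreas genes adjusted over the list alone (median 8.20, camera adjusted p = 0.00277, adjusted p = 0.585 with an estimated correlation). In 3xTg the neutrophil (median 1.07, camera adjusted p = 0.00406), Kupffer cell (median 0.33, camera adjusted p = 0.00105), stellate cell (median 0.34, camera adjusted p = 4.40e-07), endothelial (median 0.17, camera adjusted p = 0.00171) and cholangiocyte (median 0.66, camera adjusted p = 0.00391) lists were higher and the cell cycle list lower (median -0.52, camera adjusted p = 1.77e-06), with adjusted p = 0.0913 to 0.351 under an estimated correlation. The Kupffer cell call was lost without 3xTg MCT replicate 1 (camera adjusted p = 0.455) and the endothelial call without the pancreas-holding libraries (camera adjusted p = 0.0561). In WT the stellate cell list was higher (median 0.31, camera adjusted p = 1.23e-07, adjusted p = 0.172 with an estimated correlation). T and NK cell (median 0.51, camera adjusted p = 0.00688) and endothelial markers (median 0.22, camera adjusted p = 1.23e-05) were higher in WT and cell cycle genes lower (median -0.33, camera adjusted p = 0.00323), with adjusted p = 0.218 to 0.811 under an estimated correlation. The T and NK cell call was lost without WT MCT replicate 2 (camera adjusted p = 0.277). The WT adipocyte list was also higher (median 2.77, camera adjusted p = 0.0116, adjusted p = 0.420 with an estimated correlation). The adipocyte call was lost without WT MCT replicate 3 or 4 (adjusted p = 0.0668 and 0.0525). For the difference between genotypes in the MCT response edgeR called no gene, with 287 at an unadjusted p under 0.05, and DESeq2 called 0. The MCT response of the lipogenesis list differed between genotypes (median -0.69, camera adjusted p = 2.58e-10, adjusted p = 0.509 with an estimated correlation). On MCT itself the list was not called between genotypes (3xTg against WT, median -0.10, camera adjusted p = 0.761). On control diet it was higher in 3xTg (median 0.47, camera adjusted p = 6.31e-07, adjusted p = 0.207 with an estimated correlation). Setting a called list against an uncalled one is not a test, so whether the control livers carry the difference in response was not tested.

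**Figure D3:**
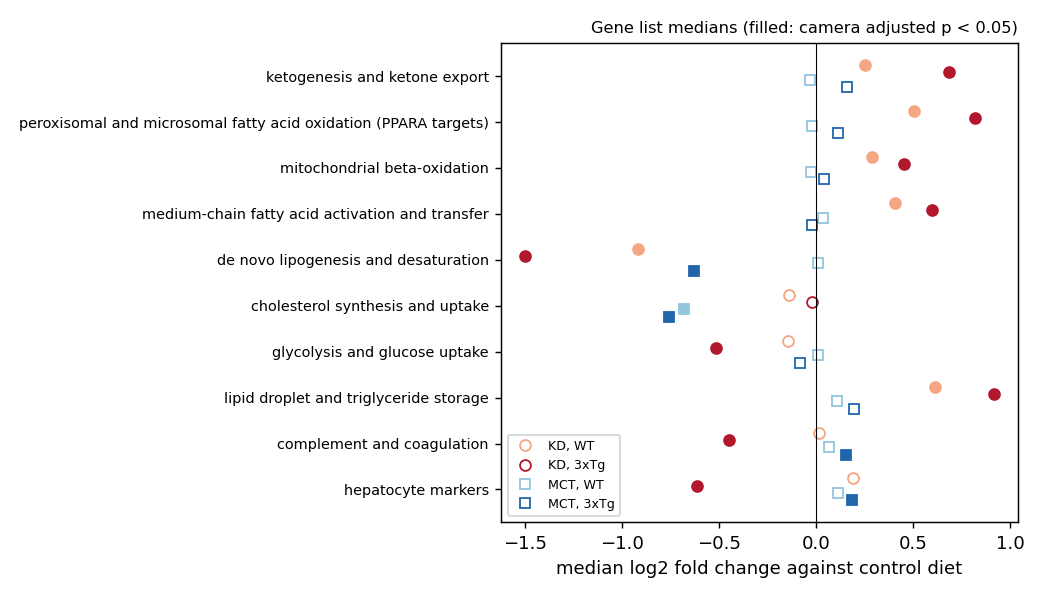
Median log2 fold change against control diet (horizontal axis) of 10 gene lists for KD and MCT in WT and 3xTg. Each symbol is the median over a list's measured genes and filled symbols have a camera adjusted p under 0.05 with the preset correlation. In 3xTg the lipogenesis median is -1.50 on KD and -0.63 on MCT, and the cholesterol median is -0.02 and -0.76.

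Set directly against MCT, KD in WT raised Mogat1 (3.73 ± 0.34, adjusted p = 2.05e-06), Sema5b (3.91 ± 0.57, adjusted p = 0.00282) and Kbtbd11 (3.00 ± 0.40, adjusted p = 0.000992) and lowered Scd1 (-3.76 ± 0.56, adjusted p = 0.00298) and Lepr (-1.90 ± 0.33, adjusted p = 0.0145), among 24 genes, 12 in each direction. The beta-oxidation list was higher, 7 of 19 adjusted over the list alone (median 0.34, camera adjusted p = 3.69e-14, adjusted p = 0.0169 with an estimated correlation). The ketogenesis list was higher too, 1 of 7 adjusted over the list alone (median 0.31, camera adjusted p = 0.000201, adjusted p = 0.0181 with an estimated correlation). Leukocyte lists were lower, with no member called over all genes: T and NK cells (median -0.71, camera adjusted p = 1.02e-05), B and plasma cells (median -0.78, camera adjusted p = 0.000229) and dendritic cells (median -0.61, camera adjusted p = 0.000169). The exocrine pancreas list was higher (median 0.37, camera adjusted p = 3.96e-05), a call lost without the pancreas-holding libraries (camera adjusted p = 0.301). With an estimated correlation these 4 lists had adjusted p = 0.0657 to 0.524. Without WT MCT replicate 3 the count was 57, without WT MCT replicate 1 it was 11, and without WT KD replicates 2 and 3 in turn 9 and 15. Without the pancreas-holding libraries it was 8, and DESeq2 called 92.

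In 3xTg, KD against MCT raised 6 of 24 cholesterol synthesis genes, Hmgcs1 (1.96 ± 0.42, adjusted p = 0.00715) and Sqle (1.74 ± 0.36, adjusted p = 0.00559) among them. In this list 13 rose and 1 fell adjusted over the list alone (median 0.81, camera adjusted p = 3.77e-06, adjusted p = 0.311 with an estimated correlation). Of 27 complement and coagulation genes 14 fell, 20 adjusted over the list alone (median -0.60, camera adjusted p = 3.96e-14, adjusted p = 0.0479 with an estimated correlation). Of 12 hepatocyte markers 8 fell, 9 adjusted over the list alone (median -0.85, camera adjusted p = 1.47e-09, adjusted p = 0.0951 with an estimated correlation). Neat1 and Xist were higher here too, against 4.99 ± 0.453 and 149.9 ± 32.1 CPM on MCT (exact permutation p = 0.0286 each, adjusted p = 0.103). B and plasma cell markers fell in 7 of 15 cases, 10 adjusted over the list alone (median -1.40, camera adjusted p = 5.30e-08, adjusted p = 0.124 with an estimated correlation). Ms4a1, which encodes CD20, was among them (-1.93 ± 0.42, adjusted p = 0.00704). All 16 measured exocrine pancreas genes fell, although the list as a whole was not called (camera adjusted p = 0.0521), and 2 of the 4 MCT livers hold pancreas transcripts. The comparison called 1065 genes, 477 upward and 588 downward. Library-size scaling called 4386 genes, 4195 upward and 191 downward. Without 3xTg KD replicates 1, 2 or 3 or 3xTg MCT replicate 3 in turn, the counts were 596, 639, 500 and 639. Without the pancreas-holding libraries it was 287, where the calls of Hmgcs1, Sqle and Ms4a1 were lost.

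Genotype was compared on each diet, and 100 genes differed between 3xTg and WT on all 3 diets, 32 higher and 68 lower in 3xTg and none in opposite directions. On control diet 247 genes were called, 106 higher and 141 lower. Cyp2c39, a cytochrome P450, was lower in 3xTg (-4.85 ± 0.33, adjusted p = 1.40e-09) on control diet, on KD (-5.46 ± 0.34) and on MCT (-5.04 ± 0.33). Its neighbours on chromosome 19 were higher in 3xTg on control diet, KD and MCT, Cyp2c67 at 1.96, 1.27 and 1.83 and Cyp2c68 at 1.10, 0.83 and 1.14. Such close paralogs can share reads. Cyp2b9 (-9.25 ± 1.73, adjusted p = 0.00320) and Sult3a1, a sulfotransferase (-4.79 ± 0.80, adjusted p = 0.00103), were lower in 3xTg, though each has close paralogs that can share its reads. Serpina3c, of a family of close paralogs as well, was at -9.46 ± 0.51, adjusted p = 5.90e-12 on control diet. Ifi44l had no count in 3xTg and was at least 37.4-fold, 52.1-fold and 50.4-fold lower on control diet, KD and MCT, against a floor of 3 counts over the group. BC018473 had 1 count over 4 WT control livers and 427 over 4 3xTg livers (453-fold, 95% interval 80.8 to 17929, for counting error only), and was at least 215-fold and 151-fold higher on KD and MCT, where WT held none. Ctse, cathepsin E (5.43 ± 0.50, adjusted p = 2.24e-07), was higher on control diet, on KD (4.82) and on MCT (5.38 ± 0.49).

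In 3xTg against WT, App stood at 0.05 ± 0.12, -0.25 ± 0.12 and 0.09 ± 0.12 and Mapt at 0.27 ± 0.22, -0.16 ± 0.22 and 0.12 ± 0.21 on control diet, KD and MCT, none called, and no human transgene sequence was counted separately here. On control diet Acaca (1.24 ± 0.25, adjusted p = 0.00645) and Me1 (1.45 ± 0.33, adjusted p = 0.0166) were higher in 3xTg. Of 23 lipogenesis genes 4 were higher, 10 adjusted over the list alone (median 0.47, camera adjusted p = 6.31e-07, adjusted p = 0.207 with an estimated correlation). PPARA targets were lower, 1 of 26 over all genes and 10 adjusted over the list alone (median -0.48, camera adjusted p = 8.60e-08, adjusted p = 0.153 with an estimated correlation). Of 11 erythroid genes 3 were higher, 9 adjusted over the list alone (median 1.63, camera adjusted p = 6.31e-07, adjusted p = 0.167 with an estimated correlation). The Me1 call was lost without 3xTg control replicate 2 or WT control replicate 1 or 3.

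On KD 1128 genes differed between genotypes, 567 higher and 561 lower in 3xTg, and library-size scaling called 4647, 4444 higher. Of 27 complement and coagulation genes 11 were lower and 1 higher, 12 and 1 adjusted over the list alone (median -0.45, camera adjusted p = 4.04e-07, adjusted p = 0.200 with an estimated correlation). The neutrophil genes S100a8 (3.71 ± 0.66, adjusted p = 0.00148) and S100a9 (3.88 ± 0.63, adjusted p = 0.000700) were higher. Without 3xTg KD replicates 2 or 3 or WT KD replicates 2 or 3 the counts were 592, 496, 596 and 565. Without the pancreas-holding libraries it was 96, where the calls of S100a8 and S100a9 were lost. In 3xTg livers on KD Neat1 and Xist were higher, against 5.36 ± 1.32 and 169 ± 47.9 CPM in WT on KD (exact permutation p = 0.0286 each, adjusted p = 0.103). Exocrine pancreas genes were lower in 15 of 16 cases, 16 adjusted over the list alone (median -12.16, camera adjusted p = 0.0125, adjusted p = 0.850 with an estimated correlation), with 3 of the 4 WT KD livers holding pancreas transcripts. On MCT 231 genes differed, 93 higher and 138 lower, and 103 without the pancreas-holding libraries. The erythroid list was higher on MCT as well, 3 of 11 over all genes and 10 adjusted over the list alone (median 1.40, camera adjusted p = 4.00e-09, adjusted p = 0.194 with an estimated correlation). On control diet the count was 153, 145 and 147 without 3xTg control replicate 2, 3 or WT control replicate 3.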

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

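The 2 tests on pancreas transcripts were chosen after the result was seen, and so were the settings with a covariate, with offsets or without sets of libraries. The reading of the pancreas covariate as undecided and the comparison at matched numbers of livers were also chosen after the values were seen, as were the draws with a genotype offset and the splits for genes called on all 3 diets.

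A liver stood apart from its group where its gap to the nearest of the other 3 exceeded a fixed share of the group's range, a limit that chance passes in about 1 in 20 groups. Of 515 such checks on library measures and named genes 38 passed it, against 25.8 by chance, and genes with counts near 0 add ties that give a share of 1. The value given is that share. WT KD replicate 4 did so for the mitochondrially encoded share (low, 0.843), summed erythroid transcripts (high, 0.831), Chil3 (high, 1) and Adh6-ps1 (low, 0.890). WT KD replicate 1 did so for Fitm2 (high, 0.917), Ahsg (low, 0.834) and Cyp2b9 (low, 0.922). WT KD replicate 2 did so for Slc4a1 (low, 0.899). WT MCT replicate 3 did so for summed pancreas transcripts (high, 0.902), summed neutrophil transcripts (low, 0.879), Bdh1 (low, 0.862), Acadm (low, 0.914), S100a8 (low, 0.948) and Pnliprp2 (high, 0.904). WT MCT replicate 4 did so for Acpp (low, 0.942) and Cdk1 (low, 0.909). 3xTg KD replicate 1 did so for summed erythroid transcripts (low, 0.869). 3xTg KD replicate 3 did so for Fitm2 (high, 0.832). 3xTg KD replicate 2 did so for Krt23 (low, 0.986). 3xTg KD replicate 4 did so for Pnliprp2 (high, 1) and Rps13-ps1 (high, 1). WT control replicate 2 did so for summed muscle transcripts (high, 0.848), Fitm1 (low, 0.896), Ngp (high, 1), Cyp2b9 (low, 0.933) and Cyp2b13 (low, 0.894). WT control replicate 4 did so for Fgf21 (high, 0.965), BC018473 (high, 1), Rpl34 (high, 0.915) and Adh6-ps1 (high, 0.889). WT control replicate 1 did so for Me1 (low, 0.854). 3xTg control replicate 4 did so for Xist (high, 0.923), Atp2b2 (high, 0.895), Fitm2 (low, 0.846) and Rps13-ps1 (high, 1). 3xTg MCT replicate 4 did so for Khk (high, 0.844) and Serpina3c (high, 0.888). 3xTg MCT replicate 1 did so for S100a8 (high, 0.861).

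Differences between the genotypes in a diet response were called for Arl4d on KD (3.43) and for lists, given as medians. On KD these were de novo lipogenesis and desaturation (-0.51), lipoprotein and apolipoprotein (-0.58), mitochondrial respiratory chain (nuclear-encoded) (-0.28), cell cycle (0.69), complement and coagulation (-0.43), female- and male-biased hepatic genes under growth hormone (-1.14), hepatocyte markers (-0.69), Kupffer cell and macrophage markers (0.37), endothelial markers (-0.31) and exocrine pancreas markers (-12.76). On MCT they were de novo lipogenesis and desaturation (-0.69), heat shock (-0.25), interferon response (-0.54), pericentral hepatocyte genes (0.43), B and plasma cell markers (0.58) and dendritic cell and antigen presentation markers (-0.49). With library-size scaling the KD medians of the respiratory chain, complement and endothelial lists changed sign. Relative to the median of all genes they did not, which this scaling leaves nearly fixed because it shifts all genes of a contrast nearly alike. None of these 16 lists held with an estimated correlation, where adjusted p was 0.287 to 0.881.

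More genes changed with KD in 3xTg (716) than in WT (86), and with offsets for GC content and gene length the 3xTg count was still 6.30 times the WT count, which argues against such bias as the cause. A pancreas score as covariate gave a ratio of 48.4, past the bound set beforehand for excluding pancreas RNA, but 3 of 4 WT KD livers and no control liver hold pancreas RNA, so the score takes up the diet effect and the 2 cannot be told apart. Without 3xTg KD replicates 2 and 3, which hold the most neutrophil transcripts, the 3xTg count was 75, inside the range set beforehand for leukocytes as the cause, but that range set a group of 2 livers against the WT count from 4. Without each pair of WT KD livers the WT count was 4 to 16, so at matched numbers the 3xTg count was at least 4.69 times the WT count. This ratio was chosen after the values were seen, and 3 of 4 WT KD livers hold pancreas RNA. It therefore does not decide on leukocytes. Leukocytes in these 2 3xTg livers, pancreas RNA in the WT livers and a genotype effect on the KD response stay open as hypotheses. The test of the last called 1 gene, 0 to 124 without single livers and 985 with library-size scaling.

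The 100 genes that differ between genotypes on all 3 diets lie near each other more often than matched genes: 28% had another within 1 Mb, against a median of 15% and a highest value of 32% in 1000 random sets (permutation p = 0.00999), and a median of 16% and a highest value of 33% in 1000 sets of KD calls (permutation p = 0.0170). Segments of background strain that differ between the lines are a candidate explanation, though tandem gene families such as Cyp2b and Sult3a add to such proximity. Pseudogenes made up 23%, with an exact 95% interval of 15.2% to 32.5%, against 2.13% of tested genes. This interval spans the 25% set beforehand as the bound for excluding shared reads, which leaves these possible for part of the genes. An effect of the transgenes was not tested apart from these.

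Pancreas transcripts passed 100 CPM in 6 of 16 KD or MCT livers and 0 of 8 control livers. Across the 17 pancreas genes the 6 libraries correlated with a median of 0.965 (0.913 to 0.992 over 15 pairs), consistent with tissue carried along at dissection. An effect of diet stays open, as Fisher's exact test gave p = 0.0664, two-sided, with few livers.

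Chance division of the livers was judged by a bound of 5% of splits, unadjusted over the contrasts. The real split counts as 1, so 1 of 35 is the smallest share possible. At that bound chance division can be excluded for KD against control diet in WT, where 1 of 35 splits gave as many genes (86, highest other 11). The same holds for KD against control diet in 3xTg (1 of 35, 716, highest other 59). Chance division can also be excluded at that bound for KD against MCT in 3xTg (1 of 35, 1065, highest other 75), for genotype on control diet (1 of 35, 247, highest other 3) and on KD (1 of 35, 1128, highest other 449). It cannot be excluded for KD against MCT in WT (2 of 35, 24, highest other 35, from a split that puts the pancreas-holding WT livers together). For genotype on MCT as a whole it cannot be excluded either (2 of 35, 231, highest other 467). The split with 467 sets replicates 1 and 2 of both genotypes against the others. It thereby puts the pancreas-holding MCT livers together, so replicate number and pancreas RNA cannot be told apart there. For the 100 genes called on MCT that were also called in 1 direction on control diet and KD, chance division can be excluded (1 of 35 splits of the MCT livers, highest other 5). This leaves it open for the other 131. The draws for the differences between responses shuffle genotypes within each diet and so carry genotype effects, as where the draw with 493 genes for KD kept the genotypes of the KD livers. They therefore say nothing about chance for the difference in the KD response (6 of 100, 1, highest other 493). With each gene's mean genotype effect as an offset 3 of 100 draws gave as many (1, highest other 1), under the 5% bound. The exact 95% interval of this share, 0.623% to 8.52%, spans that bound, so chance stays undecided for that 1 gene. For MCT against control diet in WT (35 of 35, 0, highest other 15) and 3xTg (35 of 35, 0, highest other 2) the real count was 0, as it was for the difference in the MCT response (100 of 100, highest other 169, or 25 with the offset). Each split then gives as many by construction, so the splits say nothing about chance there.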

How the results depend on the processing

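Sign changes were counted for named genes called in the main fit or in the alternative, and all but 2 such values kept their direction. Changes of sign in genes called in neither were not counted. With library-size scaling 19 of 156 called list medians changed sign, 11 calls were lost and no camera direction changed. No median changed sign relative to the median of all genes. Camera directions and such relative signs say little here, as this scaling shifts all genes of a contrast nearly alike. The settings added after the data were seen are the legacy fit, library-size scaling, the covariates, the offsets and the left-out library sets. App, KD against MCT in 3xTg, turned to 0.30 with library-size scaling, where all genes moved to 0.43, and S100a9 in that contrast to -0.14 without 3xTg KD replicates 2 and 3. The causes of the moves below were not tested, except that leaving libraries out lowers the number of livers and library-size scaling shifts all genes.

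With no expression filter MCT in WT gave 1 gene and the KD response difference 7. Not every pair of libraries sharing a number correlated above 0.1 (25 of 60, mean 0.0487), so the numbers were not taken to pair them. With different numbers it was 39 of 180 (mean -0.0159), so a shared structure of some libraries stays open. Of 24 libraries 7 correlated best with their own number, and the replicate block gave 9 genes for the KD response difference. Fitting the compared groups alone gave 141 genes for KD in WT, 7 and 444 for KD against MCT in WT and 3xTg, 722 and 82 for genotype on KD and MCT, and 55 for the KD response difference. DESeq2 gave 266 for KD in WT, 18 and 24 for MCT in WT and 3xTg, 92 for KD against MCT in WT, 385 for genotype on control diet and 253 for the KD response difference. Its overlaps were 84 between KD calls, 7 between MCT calls, and 16 and 6 between KD and MCT in WT and 3xTg. Estimated list correlation left 0, 6, 0, 0, 4, 2, 0, 0, 0, 0 and 0 lists across the 11 contrasts, against 12, 15, 9, 20, 15, 23, 11, 16, 19, 10 and 6.

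The legacy fit gave 53 for KD in WT. Library-size scaling gave 1762 for KD in 3xTg, 4386 for KD against MCT in 3xTg, 4647 for genotype on KD and 985 for the KD response difference, with 973 higher. The pancreas covariate gave 14 for KD in WT, 489 for KD against MCT in 3xTg, 386 for genotype on KD and 0 for the KD response difference. Without pancreas-holding libraries KD in WT gave 4, KD against MCT 8 in WT and 287 in 3xTg, genotype 96 on KD and 103 on MCT, and KD calls shared between genotypes 3. Without 3xTg KD replicates 2 and 3 KD in 3xTg gave 75, KD against MCT 227, genotype on KD 142 and the KD response difference 0. GC and length offsets gave 156 for KD in WT, 45 for KD against MCT in WT, 372 for genotype on control diet and 47 for the KD response difference. The clock covariate gave 144 for KD in WT and 0 for the KD response difference.

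Leaving out 1 library gave 13 to 49 for KD in WT, 270 to 879 for KD in 3xTg, 0 to 1 for MCT in WT, 0 to 0 for MCT in 3xTg, and 9 to 57 and 500 to 1176 for KD against MCT in WT and 3xTg. It gave 145 to 212, 496 to 1296 and 155 to 225 for genotype on control diet, KD and MCT, and 0 to 124 for the KD response difference and 0 to 0 for the MCT one. Shifted lists ranged 5 to 16 for MCT in WT, 11 to 21 for genotype on MCT and 4 to 10 for the MCT response difference. Shared calls ranged 9 to 37 for KD and 0 to 1 for KD and MCT in WT. Of 4720 values of named genes under these omissions 782 lost and 6 gained their call. The control livers shared by KD and MCT give a covariance of fold changes of 0.0761 in WT and 0.0769 in 3xTg with no effect, against 0.351 and 0.0573 observed and 0.325 and -0.0297 with the controls split. Single livers carry these values: in WT it was 0.0803 without WT MCT replicate 3, near the no-effect value, and 0.0508 without pancreas-holding libraries. In 3xTg it was 0.177 without 3xTg control replicate 1, 0.0145 without 3xTg KD replicate 4 and 0.107 without pancreas-holding libraries.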

Other observations

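The skeletal muscle list and the tests on Ptprc and summed Kupffer cell transcripts were chosen after the data were seen, and the other lists before. Other cells and tissues varied between livers. Skeletal muscle transcripts ranged from 0.422 to 311 CPM per library, with 311 in 3xTg MCT replicate 4, 253 in 3xTg KD replicate 4 and 216 in WT KD replicate 4. Adipocyte transcripts reached 104 CPM in 3xTg KD replicate 1, and 15.6 CPM was the lowest value.

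On KD, 5 of 21 cell cycle genes were higher in 3xTg than in WT, 8 adjusted over the list alone (median 1.08, camera adjusted p = 0.000393, adjusted p = 0.440 with an estimated correlation), with Cdk1 (1.97 ± 0.50, adjusted p = 0.0175) and Top2a (1.64 ± 0.46, adjusted p = 0.0309), 2 genes of dividing cells. The list's call was lost with library-size scaling (camera adjusted p = 0.0903). Leukocyte and macrophage transcripts were higher in the same comparison. Ptprc averaged 69.3 ± 45.8 CPM in 3xTg KD livers against 12.9 ± 2.23 in WT KD livers, and summed Kupffer cell transcripts 1594 ± 262 against 840.4 ± 94.0 (SD, n = 4, exact permutation p = 0.0286 each, adjusted p = 0.103). Summed neutrophil transcripts averaged 56.6 against 4.22 CPM (exact permutation p = 0.0286, adjusted p = 0.206). Of 18 Kupffer cell and macrophage markers 3 were higher (median 0.35, camera adjusted p = 0.000677, adjusted p = 0.440 with an estimated correlation), a call lost without 3xTg KD replicates 2 and 3 (camera adjusted p = 0.106). Ddit4, a stress-induced gene, was higher too (2.79 ± 0.42, adjusted p = 0.000272). Igfbp2 was lower (-1.84 ± 0.33, adjusted p = 0.00138). Circadian clock genes were not shifted as a list in any of the 11 contrasts, and in 3xTg KD against control diet none of 18 was called (median -0.03, camera adjusted p = 0.529). Camera looks for a shift of the list in a common direction, so it cannot decide whether clock phase differed between livers. Across libraries the clock genes Dbp and Arntl ranged from 1.82 to 106 CPM and from 0.362 to 23.6 CPM. Without the pancreas-holding libraries, which leaves 1 WT KD liver, the calls of Cdk1, Top2a, Ddit4 and Igfbp2 were lost.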
